A study of Caenorhabditis elegans with 6 samples.

How the data were processed

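RNA was sequenced from whole adult Caenorhabditis elegans of the N2 strain in 6 samples. L4 larvae were fed bacteria that make double-stranded RNA, and adults of the next generation were collected. The samples fell into 2 groups of 3 biological replicates, control worms fed RNA against tag-208 (now called sorb-1) and worms fed RNA against prx-5. The name sorb-1 for tag-208 was taken from the gene names, since the deposited tables list the gene as sorb-1.

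The deposited files were 7 tables of 15796 loci each, 1 per library and 1 comparison of the groups. Per the file headers, the authors gave FPKM (fragment counts scaled by locus length and by the mapped fragments of the library) for each library and for each group. The comparison table deposited by the authors also held a log2 fold change, a test statistic as a score, and a p-value with a q-value per locus. The submitters' notes list CASAVA, Bowtie, Cufflinks and Cuffdiff without versions. The genome build, annotation and filters were not stated. Locus coordinates were compared with the WBcel235 annotation, and 14402 of 14491 single named loci carried gene identifiers found in it. Starts were moved from counting at 0 to counting at 1. A locus in these tables can span part of a gene, and where a name had several loci, the one with the largest overlap with the annotated gene stood for it in the gene lists.

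Loci were joined by position in the tables, and the labels were compared across the 7 files. For 14883 loci the labels were the same in all files, and for 913 they differed. The authors' group values were recovered from the libraries as the mean of the FPKM after 1 constant per library. These constants were 1.04, 1.08 and 1.03 for control replicates 1, 2 and 3, and 0.916, 0.977 and 0.970 for prx-5 replicates 1, 2 and 3. Where the recovered value missed the table by more than a tolerance of 2%, in 91 further loci, the values were taken not to belong together. In all, 1004 loci were left out and 14792 were used. A total of 33 values with a status of FAIL or HIDATA, of which 23 were listed at 0, were set to missing. Of the loci used, 16 lacked a library.

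FPKM were used as deposited, without the authors' constants. They were changed to log2 after a pseudocount of 1 was added, and loci with a mean of at least 1 FPKM over the 6 libraries were tested, which left 13353. The groups were compared with limma 3.58.1 in R 4.3.3 by a linear model with empirical Bayes moderation and a variance trend, and p-values were adjusted by the Benjamini-Hochberg method. A locus was called at an adjusted p under 0.05, with no limit on the fold. Fold changes are prx-5 minus control on the log2 scale, with the standard error (SE) of the moderated fit, and FPKM are given as mean ± SD with n = 3 unless stated. The replicate numbers were not used as a block, because the labels name none. The deviations of the libraries from their group, computed later, did not follow the numbers in all 3 pairs.

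Before the data were examined, 37 gene lists were fixed, and 35 with at least 5 tested members were compared with the other loci by camera, two-sided, with a preset correlation of 0.01 between genes. Lists were also tested by camera with a correlation estimated for each list, and by fry, which asks whether the members of a list move, on balance, one way. The list values of single libraries are medians of each member's log2 deviation from its control mean. For a list, "adjusted over the list alone" means that p-values were adjusted among its members.

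The genes named in the text were chosen by a rule fixed before the data were examined. They are the 2 targeted genes, the 12 largest rises and the 12 largest falls among calls whose groups did not overlap, and up to 4 members of each list with the smallest p-values. Also always given, where measured, were acs-2, fat-7, fat-5, hsp-6, hsp-60, hsp-4, hsp-16.2, gst-4, daf-22, ctl-2, prx-10, prx-11 and vit-2. Loci without a gene name and non-coding genes were left out of the ranked part. Genes outside the rule are said to be so.

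After the first results were seen, gene families were tested for an excess of called members. A family was all loci with the same letters before the hyphen in their names, with at least 5 tested, which gave 270 families over 12738 loci. The test was Fisher's exact test, one-sided, for higher and for lower calls, adjusted by Benjamini-Hochberg over both directions.

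Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a variance without a trend, sample weights, a replicate block, a fold limit, an estimated correlation, and leaving out each library in turn. Chosen after the data were seen were the authors' constants, loci of at least 200 bp, loci that cover at least 50% of their gene, all loci as listed, and a germline score as a covariate. The germline score is the mean log2 level of the germline marker list in a library.

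The tables held FPKM and no read numbers, so no counts, counting intervals or floors could be given. The depth relative to control replicate 1 was estimated from the commonest ratio between low FPKM values. It was 1.10 and 0.840 for control replicates 2 and 3, and 0.767, 1.03 and 1.26 for prx-5 replicates 1, 2 and 3. Few of the low loci lay at that ratio, from 78 of 2256 for prx-5 replicate 3 to 213 of 3316 for control replicate 3. The test was tried on simulated data with 3 libraries per group and 13340 loci, of which 200 had a simulated change. It called 20% of loci simulated at a log2 change of 1, and 74% at 2. Of loci that passed the filter, it called 23.3% at -1 and 73.2% at -2. It also called 6 of 13140 loci simulated without a change. The adjusted p depends on how many loci change, and 1162 were called in the data, so these shares need not hold there. In these simulated data camera called the 1 shifted list and 0 of the others. The noise was drawn independently for each locus, so this does not show how camera behaves where the genes of a list vary together. Tables were read in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.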

Results

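RNA-seq libraries were made from total RNA of whole adult worms. The 6 libraries fell into 2 groups of 3 biological replicates, labelled control (tag-208 RNAi) and prx-5 RNAi. The number of reads per library is unknown, and the estimated depth relative to control replicate 1 ranged from 0.767 in prx-5 replicate 1 to 1.26 in prx-5 replicate 3. The 20 loci with the highest FPKM held between 10.8% and 13.96% of the FPKM of a library. Pearson correlations between libraries across loci, which are not independent replicates, ranged from 0.896 to 0.966. The first principal component held 52.1% of the variance across 13340 loci. On it, control replicates 1, 2 and 3 lay at -51.3, -15.4 and -54.8, and prx-5 replicates 1, 2 and 3 at 7.33, 54.3 and 59.9. The second held 19.8% and set control replicate 2 (-55.7) apart from prx-5 replicate 1 (37.7).

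The comparison asked which transcripts differ between RNAi of prx-5, the receptor that brings most enzymes into the peroxisome, and RNAi of sorb-1. Both groups had a targeted gene, so a difference can come from either group. RNA of prx-5 itself was higher in the libraries labelled prx-5 RNAi, the opposite direction to a knockdown of its RNA, so the directions below are those of the labels alone. The gene (WBGene00004194) was measured at a locus on chromosome II from 8704855 to 8706817 in coordinates that match WBcel235, which covered 98.4% of the gene. It had 4.24 ± 0.65 FPKM in the control-labelled libraries and 19.9 ± 4.45 in the prx-5-labelled libraries (SD, n = 3), 4.69-fold by the means. Its log2 fold change was 1.98 ± 0.22 (SE), with an adjusted p of 0.00869. All 3 prx-5-labelled values (14.9, 21.3 and 23.5) lay above all 3 control values (4.48, 4.73 and 3.50). In the authors' own table, prx-5 had a log2 fold change of 2.097 with a q of 0.00101. The control's target sorb-1 (WBGene00012891, chromosome IV) had 10.5 ± 3.11 FPKM in the control-labelled libraries and 18.03 ± 6.60 in the prx-5-labelled libraries (SD, n = 3). Its log2 fold change of 0.72 ± 0.31 (SE) did not pass the test (adjusted p = 0.232), though all 3 prx-5-labelled values (13.6, 14.8 and 25.6) lay above all 3 control values (11.5, 12.9 and 6.96).

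In the libraries labelled prx-5 RNAi, genes of peroxisomal lipid breakdown and import and the intestine markers rose. Some autophagy and lysosome genes and members of several defence gene families rose as well. A set of cuticle collagens, fat-7 and acdh-2 fell. Of 13353 loci tested, 1162 changed at an adjusted p under 0.05, 1002 higher and 160 lower. Of these, 968 changed by at least 1 on the log2 scale, 860 higher and 108 lower. The groups did not overlap in any of the 1162, nor in 26.97% of all tested loci, where chance gives 10%. Higher loci made up 86.2% of the calls. The deposited FPKM lack the authors' joint scaling, which moved the log2 fold changes by a median of -0.13 and left 713 changed loci, 521 higher and 192 lower (73.1% higher). Median-ratio scaling moved them by a median of -0.11 and left 697 (73.3% higher), and quantile normalization left 775 (69.2% higher). The count depended on single libraries, in fits that use fewer samples. It was 306, 866 and 78 without control replicates 1, 2 and 3. Without prx-5 replicates 1, 2 and 3 it was 1848, 155 and 123. Of the calls, 720 were kept without control replicate 2 and 1087 without prx-5 replicate 1, against 77 without control replicate 3. No called locus had the opposite sign in any of these fits where it was tested. Since the groups of these loci did not overlap, leaving out a library could not have turned a sign. The authors' table called 1918 of the tested loci significant, 1271 higher and 647 lower. It shared 958 calls with the limma fit, all 958 in the same direction, and 204 were called by limma alone. Both comparisons used the same 6 libraries, so the shared direction is not independent support. Of genes given below as not past limma, the authors called acs-2, fat-5, hsp-60, hsp-4, unc-54, msp-3, nspd-7, noah-1, rps-27 and vit-1. They did not call hsp-6, hsp-16.2, cysl-3 or prx-19.

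The peroxisomal fatty acid breakdown genes, which also shorten the side chains of ascaroside pheromones, rose in the prx-5-labelled libraries. Of 12 tested members, 9 rose and 0 fell (9 adjusted over the list alone). The median log2 fold change was 2.84, against 1.52 for the intestine markers in the same libraries. The acyl-CoA oxidase gene F58F9.7 (now acox-3) went from 9.27 ± 2.65 to 217 ± 77.0 FPKM (SD), with a log2 fold change of 4.39 ± 0.29 (adjusted p = 0.00303). The oxidase genes F59F4.1 (now acox-1.6) and acox-5 (now acox-1.5) rose by 3.48 ± 0.26 and 4.62 ± 0.63. The thiolase daf-22, which carries out the last step of the cycle, went from 39.1 ± 6.63 to 304 ± 78.9 FPKM (2.91 ± 0.23, adjusted p = 0.00417). The acyl-CoA synthetase acs-7 rose by 3.88 ± 0.33. The camera adjusted p was 2.44e-09 for the list, and an adjusted p of 0.443 with an estimated correlation. The list medians of prx-5 replicates 1, 2 and 3 were 2.51, 3.22 and 2.84 above the control mean. Leaving out any 1 library kept at least 8 of the 9 calls.

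The import machinery of the peroxisome rose as well, about as much as the intestine markers (median 1.52) in the same libraries. The list left out prx-5, and of 6 tested members 5 rose and 0 fell (5 adjusted over the list alone), with a median log2 fold change of 1.63. The docking factor prx-13 went from 7.25 ± 0.23 to 31.2 ± 6.49 FPKM (SD), a log2 fold change of 1.95 ± 0.19 (adjusted p = 0.00585). The genes prx-12, prx-3 and prx-6 rose by 1.77 ± 0.27, 1.77 ± 0.27 and 1.32 ± 0.19. The fifth was prx-1, at 1.496 ± 0.254 (adjusted p = 0.0198), named after its values were seen. The remaining member prx-19, also named after its values were seen, had 157 ± 20.7 and 159 ± 7.31 FPKM (log2 0.02 ± 0.15, adjusted p = 0.949), and its sign turned under the authors' constants (-0.11) and median-ratio scaling (-0.09). Of the genes always given, prx-10 had no locus of its own, and prx-11 lay under the filter, at 0.817 and 0.912 FPKM in the authors' table (q = 0.911). By camera, the adjusted p was 6.77e-05 (adjusted p = 0.443 with an estimated correlation). The calls depended on single libraries, with 1 of the 5 left without control replicate 3, prx-5 replicate 2 or prx-5 replicate 3.

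Other peroxisomal enzymes and transporters followed, with 11 of 17 tested members higher and 0 lower (12 adjusted over the list alone) and a median log2 fold change of 1.62. The reductase gene dhrs-4 went from 15.4 ± 2.16 to 99.7 ± 8.04 FPKM (SD), a log2 fold change of 2.62 ± 0.16 (adjusted p = 0.00303). The peroxisomal catalase ctl-2, which breaks down hydrogen peroxide, rose by 2.74 ± 0.25, the transporter gene pmp-4 by 3.10 ± 0.26, and the protease gene Y75B8A.4 (now lonp-2) by 3.30 ± 0.26. With camera, the list had an adjusted p of 4.85e-09 (adjusted p = 0.443 with an estimated correlation). Of the 11 calls, 4 were left without control replicate 3 and 5 without prx-5 replicate 2. The rise of this list was also about that of the intestine markers.

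**Figure D1:**
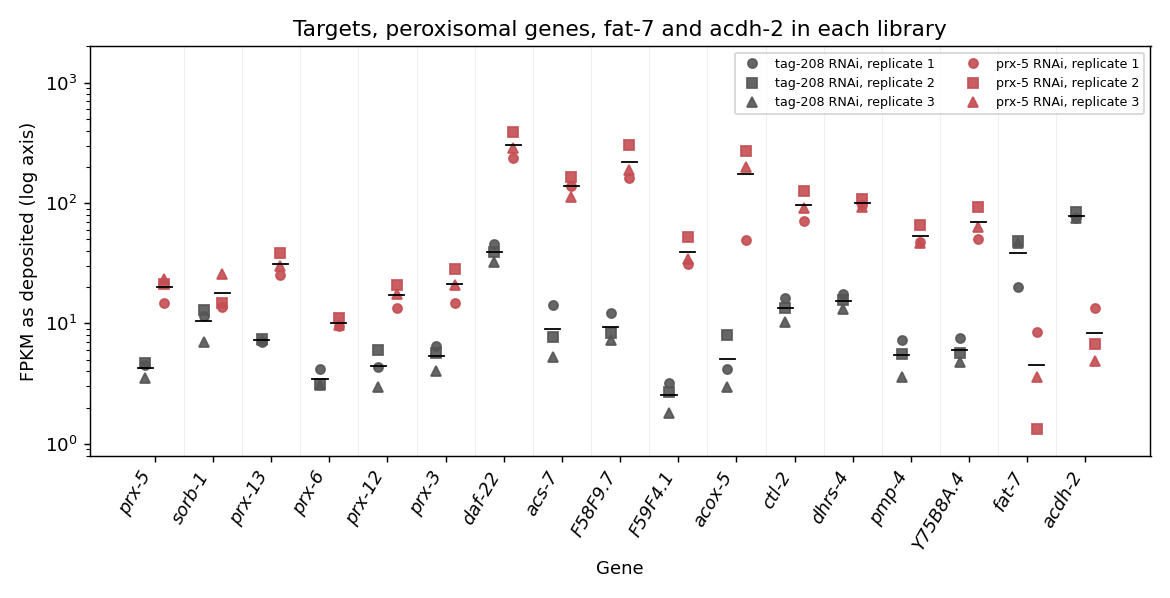
FPKM as deposited (log axis) of the 2 targeted genes, peroxisomal genes, fat-7 and acdh-2 in each library, with grey symbols for control-labelled and red symbols for prx-5-labelled replicates, and short black lines at the group means. The prx-5 values of 14.9 to 23.5 in its own group lie above the control values of 3.50 to 4.73, and fat-7 and acdh-2 lie lower in the prx-5-labelled libraries.

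Among lipid and NHR-49-dependent genes outside the peroxisome, changes went both ways. The desaturase fat-7, which makes oleic acid from stearic acid, fell by 2.98 ± 0.55 on the log2 scale (38.4 ± 15.9 to 4.48 ± 3.68 FPKM, adjusted p = 0.0247), and hacd-1 and fmo-2 rose by 2.78 ± 0.40 and 1.53 ± 0.28. With these, 2 of 10 tested members of the NHR-49-dependent list rose and 1 fell (4 higher and 1 lower adjusted over the list alone). That list is not limited to lipid enzymes. Camera gave an adjusted p of 0.186 (0.0439 with quantile normalization and 0.482 with an estimated correlation). The list passed fry as higher (fry adjusted p = 0.0109). The acyl-CoA synthetase acs-2 had 16.7 ± 12.2 and 36.5 ± 15.8 FPKM (adjusted p = 0.319), with a control range from 2.63 to 24.96. The desaturase fat-5 had 46.4 ± 4.18 and 30.01 ± 12.1 FPKM (adjusted p = 0.245). The authors' comparison called acs-2 higher (log2 1.00, q = 0.00101) and fat-5 lower (log2 -0.76, q = 0.0338). Of the 3 limma calls in the NHR-49 list, 0 were kept without control replicate 3, prx-5 replicate 2 or prx-5 replicate 3.

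Of 21 genes of fatty acid synthesis, elongation and desaturation, 6 rose and 1, fat-7, fell (11 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.49, against 1.52 for the intestine markers. The acetyl-CoA carboxylase pod-2 rose by 1.33 ± 0.19, the desaturase fat-3 by 1.41 ± 0.16 and the elongase elo-2 by 1.08 ± 0.20. For this list camera gave an adjusted p of 0.00244 (adjusted p = 0.482 with an estimated correlation), and 0 of the 7 calls remained without control replicate 3 and 4 with the authors' constants. Of 16 mitochondrial fatty acid breakdown genes, 3 rose, ech-7 by 1.68 ± 0.21, acdh-10 by 0.57 ± 0.13, and hacd-1 (3 adjusted over the list alone, camera adjusted p = 0.440). None of the 3 calls remained without control replicate 3. The median of that list, 0.13, turned to -0.01 with the authors' constants. The acyl-CoA dehydrogenase acdh-2, outside that list, fell by 3.18 ± 0.32 (77.7 ± 5.24 to 8.33 ± 4.45 FPKM, adjusted p = 0.00654). Of 20 lipases, 1 rose, the lysosomal lipase lipl-5 (1.31 ± 0.31, adjusted p = 0.0448), and 0 passed adjusted over the list alone. The call of lipl-5 was kept without control replicate 1 but lost without any other single library and with the authors' constants. The lipase list missed the camera threshold (adjusted p = 0.0643, and 0.482 with an estimated correlation). It passed with the replicate block (0.0347), median-ratio scaling (0.0244), sample weights (0.04065) and the authors' constants (0.0236). It also passed with loci covering at least 50% of their gene (0.0408) and without control replicate 2 (0.0164).

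The markers of the intestine all rose, and intestinal genes outside this list were not tested as a group. Of 12 tested intestine markers, 12 rose (12 adjusted over the list alone), with a median log2 fold change of 1.52, among them the gut proton pump vha-6 (48.6 ± 10.5 to 237 ± 99.2 FPKM, SD, log2 2.19 ± 0.34), the gut transcription factor elt-7 (1.47 ± 0.24) and the aspartyl protease asp-1 (2.53 ± 0.38). The list medians of prx-5 replicates 1, 2 and 3 lay 1.03, 1.92 and 1.69 above the control mean. The camera adjusted p was 4.85e-09 (adjusted p = 0.482 with an estimated correlation). Of the 12 calls, 2 remained without control replicate 1, 0 without control replicate 3, prx-5 replicate 2 or prx-5 replicate 3, and 6 with the authors' constants. Of 21 autophagy and lysosome genes, 5 rose (9 adjusted over the list alone), with a median log2 fold change of 0.42. They included the lysosomal proteases asp-3 (2.36 ± 0.38), asp-4 (1.32 ± 0.23) and cpl-1 (1.12 ± 0.22), and the autophagy receptor sqst-1 (1.96 ± 0.34). By camera, the adjusted p was 1.36e-04 (adjusted p = 0.482 with an estimated correlation), and 0 of the 5 calls remained without control replicate 3, prx-5 replicate 2 or prx-5 replicate 3, and 3 with the authors' constants.

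Defence gene families had many higher members, while the markers of the intestine, where many such genes are expressed, were higher by a median of 1.52 in the same libraries. Of 71 lysozyme, saposin-like and antimicrobial peptide genes, 20 rose and 4 fell (24 and 4 adjusted over the list alone), with a median log2 fold change of 0.61. The lysozyme ilys-3 went from 0.772 ± 0.411 to 13.4 ± 1.87 FPKM (SD, log2 3.05 ± 0.25), spp-18 rose by 2.90 ± 0.27, and irg-3 rose by 2.45 ± 0.24. The saposin-like gene spp-21 was listed at 0 in the 3 control-labelled libraries and had 7.17 ± 2.32 FPKM in the prx-5-labelled ones. With camera, this list had an adjusted p of 0.00203 (adjusted p = 0.623 with an estimated correlation), which was 0.381 with the germline score as a covariate. Of 99 C-type lectin genes, 30 rose and 1 fell (40 and 3 adjusted over the list alone), with a median of 0.49, among them clec-65 (2.404 ± 0.314) and clec-205 (2.19 ± 0.24). For this list camera gave an adjusted p of 4.54e-05 (adjusted p = 0.482 with an estimated correlation). Of 13 pals genes, a family that responds to intracellular pathogens, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.12. Among the 6 was F22G12.7 (now pals-15), measured at a locus that covered 0% of the annotated gene. C29F9.4 (now pals-24) rose by 2.19 ± 0.32 and C17H1.7 (now pals-6) by 2.21 ± 0.46. The camera adjusted p was 3.40e-04 (adjusted p = 0.482 with an estimated correlation). Without control replicate 3, 5 of the 24 lysozyme and peptide calls, 3 of the 31 lectin calls and 0 of the 6 pals calls were left. The authors' constants left 18, 20 and 2 of these calls, median-ratio scaling 18, 19 and 2, and the germline score 14, 12 and 2.

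Detoxification genes moved in both directions, mostly up, in the same libraries in which the intestine markers were higher by a median of 1.52. Of 49 UDP-glucuronosyltransferase genes, which attach sugars to foreign molecules, 11 rose and 3 fell (15 and 4 adjusted over the list alone). The gene ugt-62 went from 38.7 ± 15.2 to 342 ± 181 FPKM (SD, log2 3.07 ± 0.44). By camera, the adjusted p was 0.00343 (adjusted p = 0.623 with an estimated correlation), which was 0.0852 without control replicate 3 and 0.162 with the germline score. Of 48 cytochrome P450 genes, 10 rose and 1 fell (13 and 2 adjusted over the list alone). They included cyp-32B1 (2.56 ± 0.28) and cyp-13A5 (3.31 ± 0.41), and camera gave an adjusted p of 0.0120 (adjusted p = 0.482 with an estimated correlation), which was 0.0938 with sample weights and 0.0913 with the germline score. Of 36 glutathione S-transferase genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.693). There gst-6 rose by 2.95 ± 0.39 and gst-22 by 1.95 ± 0.29. The oxidative stress reporter gene gst-4 fell by 0.92 ± 0.22 (21.2 ± 4.78 to 10.7 ± 1.94 FPKM, adjusted p = 0.0473), a call kept without prx-5 replicate 1 but lost without any other single library. Without control replicate 3, 1 of the 14 glucuronosyltransferase calls, 2 of the 11 P450 calls and 0 of the 6 transferase calls remained, and with the authors' constants 11, 8 and 5.

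Stress responses outside these families showed few calls. Of 12 genes of the mitochondrial unfolded protein response, 0 changed (0 adjusted over the list alone, camera adjusted p = 0.520), and its chaperones hsp-6 and hsp-60 had log2 fold changes of 0.21 ± 0.23 and -0.64 ± 0.25 (adjusted p = 0.636 and 0.200). Of 18 genes of the endoplasmic reticulum response, 0 changed (0 adjusted over the list alone, camera adjusted p = 0.491). There hsp-4 stood at -0.53 ± 0.24 (adjusted p = 0.255). The authors' comparison called hsp-60 (log2 -0.74) and hsp-4 (log2 -0.65) lower (q = 0.00334 each), and did not call hsp-6 (q = 0.919). Of 11 heat shock genes, 0 changed (0 adjusted over the list alone). That list passed camera as lower (median -0.29, adjusted p = 0.0364), but not with an estimated correlation (adjusted p = 0.623), quantile normalization (0.172), a mean of at least 5 FPKM (0.0554) or the germline score (0.241), nor without control replicate 1 (0.104), control replicate 3 (0.101) or prx-5 replicate 2 (0.342). Its member hsp-16.2 had 3.78 ± 0.50 and 5.03 ± 4.42 FPKM, with a log2 fold change of 0.04 ± 0.55 whose sign turned under each scaling tried. Of 20 oxidative stress and SKN-1 targets, gst-6 rose and gst-4 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.618). Of 12 DAF-16-associated genes, 1, ctl-2, rose (1 adjusted over the list alone). Camera gave that list an adjusted p of 0.0847, which was 0.0276 with quantile normalization and 0.04685 without prx-5 replicate 2. It was 0.482 with an estimated correlation, and the list passed fry as higher (fry adjusted p = 0.0109). Of 8 hypoxia-inducible genes, 0 changed (3 higher adjusted over the list alone, camera adjusted p = 0.132), with cysl-3 at 0.51 ± 0.13 (adjusted p = 0.0606). Of 11 genes of the propionate shunt and methionine cycle, 0 changed (0 adjusted over the list alone, camera adjusted p = 0.482). Over all tested loci, limma gave 2929 at an unadjusted p under 0.05.

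A set of cuticle collagens fell. Of 107 tested collagen genes, 0 rose and 19 fell (2 and 20 adjusted over the list alone). The adult-stage collagen col-19 fell by 1.77 ± 0.19 (997 ± 35.9 to 294 ± 54.1 FPKM, SD), and col-124 fell by 2.37 ± 0.20 (1887 ± 42.2 to 369 ± 70.4 FPKM, adjusted p = 0.00457). The median of the list was above 0 (0.32) and so was the mean (0.19), while camera read it as lower (adjusted p = 0.0448, and adjusted p = 0.759 with an estimated correlation). That camera call lay close to the threshold. It was lost with the authors' constants (0.398), median-ratio scaling (0.322), quantile normalization (0.407), the replicate block (0.1585), a pseudocount of 0.1 (0.0596) or 0.5 (0.0529), no filter on low values (0.0723) and a mean of at least 5 FPKM (0.0626). It was also lost without prx-5 replicate 1 (0.374) and, with the direction turned, with sample weights (0.630) and without control replicate 2 (0.109). Of the 19 calls, 3 remained without control replicate 3, 3 without prx-5 replicate 2 and 2 without prx-5 replicate 3. The list medians of control replicates 1, 2 and 3 were -0.22, 1.36 and -0.82, and those of prx-5 replicates 1, 2 and 3 were -0.34, 0.91 and 0.50. Of 15 larval moulting markers, 0 changed (0 adjusted over the list alone). Camera gave that list an adjusted p of 0.230 (0.759 with an estimated correlation), which was 0.0472 with sample weights and 0.00213 without control replicate 2. There noah-1 had 6.16 ± 4.25 and 14.1 ± 4.15 FPKM (adjusted p = 0.144), and the list median of control replicate 2, 0.91, lay with those of prx-5 replicates 2 and 3 (1.07 and 0.89).

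Muscle and neuron markers gave 1 call each. Of 13 muscle markers, 1, the troponin T gene mup-2, fell by 1.07 ± 0.18 (299 ± 20.1 to 143 ± 26.4 FPKM, adjusted p = 0.0183), and 8 fell adjusted over the list alone. The median of the list was -0.67, and the myosin gene unc-54 stood at -0.67 ± 0.18 (adjusted p = 0.0652). With camera, the list had an adjusted p of 5.72e-06 (adjusted p = 0.443 with an estimated correlation), and mup-2 was not called without control replicates 1 or 3 or prx-5 replicates 2 or 3. Of 14 neuron markers, 1, unc-64, rose by 0.78 ± 0.18 (1 adjusted over the list alone), a call kept without prx-5 replicate 1 but lost without any other single library and under each scaling tried. The neuron list had a camera adjusted p of 0.0120 (adjusted p = 0.623 with an estimated correlation), which was 0.0716 without control replicate 1, 0.124 without prx-5 replicate 3 and 0.236 with the germline score. Of 20 genes of the RNA interference machinery, 2 rose, the gut uptake receptor sid-2 (1.80 ± 0.35) and the argonaute sago-1 (0.96 ± 0.17) (2 adjusted over the list alone, camera adjusted p = 0.459), and neither call held without control replicates 1 or 3 or prx-5 replicates 2 or 3. Quantile normalization kept sid-2 alone, and median-ratio scaling, the authors' constants and the germline score kept sago-1 alone.

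Reproductive genes gave no calls beyond 2 vitellogenins. Of 41 sperm genes, 0 changed (0 adjusted over the list alone), with a median of -1.01 (camera adjusted p = 2.31e-10, and adjusted p = 0.482 with an estimated correlation). The sperm genes msp-3 and nspd-7 stood at -1.49 ± 0.36 and -1.103 ± 0.282 (adjusted p = 0.0512 and 0.0592). The sperm list medians of control replicates 1, 2 and 3 were -0.23, 0.93 and -0.57, and those of prx-5 replicates 1, 2 and 3 were -1.49, -0.49 and -1.01. Of 20 germline markers and 18 oocyte and eggshell markers, 0 changed in either list (0 adjusted over each list alone), with medians of -0.27 and -0.18. Camera gave adjusted p of 9.45e-04 and 0.0238 (adjusted p = 0.623 and 0.734 with an estimated correlation). The germline call was lost without prx-5 replicate 3 (0.0501). The oocyte call was lost with quantile normalization (0.849), at a mean of at least 5 FPKM (0.0638), and without control replicate 3 (0.255), prx-5 replicate 2 (0.0507) or prx-5 replicate 3 (0.219). The germline list medians were 0.14, -0.32 and 0.20 in control replicates 1, 2 and 3, and 0.09, -0.29 and -0.55 in prx-5 replicates 1, 2 and 3. Of 7 early embryo markers, 0 changed (0 adjusted over the list alone, camera adjusted p = 0.958). Of 6 vitellogenins, which carry yolk to oocytes, 2 rose (2 adjusted over the list alone), vit-2 (1.21 ± 0.27, adjusted p = 0.0478) and vit-6 (1.37 ± 0.28, adjusted p = 0.0384). Their values in prx-5 replicate 3 were missing (n = 2), and neither call held with the authors' constants or without any library except prx-5 replicate 1. The genes vit-1 and vit-3 stood at -1.47 ± 0.75 and -1.93 ± 0.94 (adjusted p = 0.308 and 0.290), with vit-3 at 1025 FPKM in prx-5 replicate 1 and at 57.5 and 139 in replicates 2 and 3. With too few complete members, the vitellogenins were not tested by camera.

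Ribosomal, proteasome and respiratory chain lists passed camera as lower with the preset correlation, with no single call, and histones did not pass. Of 50 cytosolic ribosomal protein genes, 0 changed (0 adjusted over the list alone), with a median of -0.53, and rps-27 stood at -0.65 ± 0.28 (adjusted p = 0.228). The camera adjusted p was 2.03e-11 (adjusted p = 0.482 with an estimated correlation). The list medians of prx-5 replicates 1, 2 and 3 were -0.06, -0.86 and -0.68, and those of control replicates 1, 2 and 3 were 0.13, -0.19 and 0.08. Of 27 proteasome subunits and 37 nuclear-encoded respiratory chain genes, 0 changed in either list (0 adjusted over each list alone), with medians of -0.35 and -0.25. Camera gave adjusted p of 2.23e-06 and 2.48e-06 (adjusted p = 0.623 and 0.482 with an estimated correlation). The proteasome medians of prx-5 replicates 1, 2 and 3 were 0.05, -0.48 and -0.66, and the median of control replicate 2 was -0.27. Of 27 histone genes, 0 changed (0 adjusted over the list alone, camera adjusted p = 0.520). Of 4 mitochondrially encoded genes, too few for camera, 0 changed (0 adjusted over the list alone, median -0.13).

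**Figure D2:**
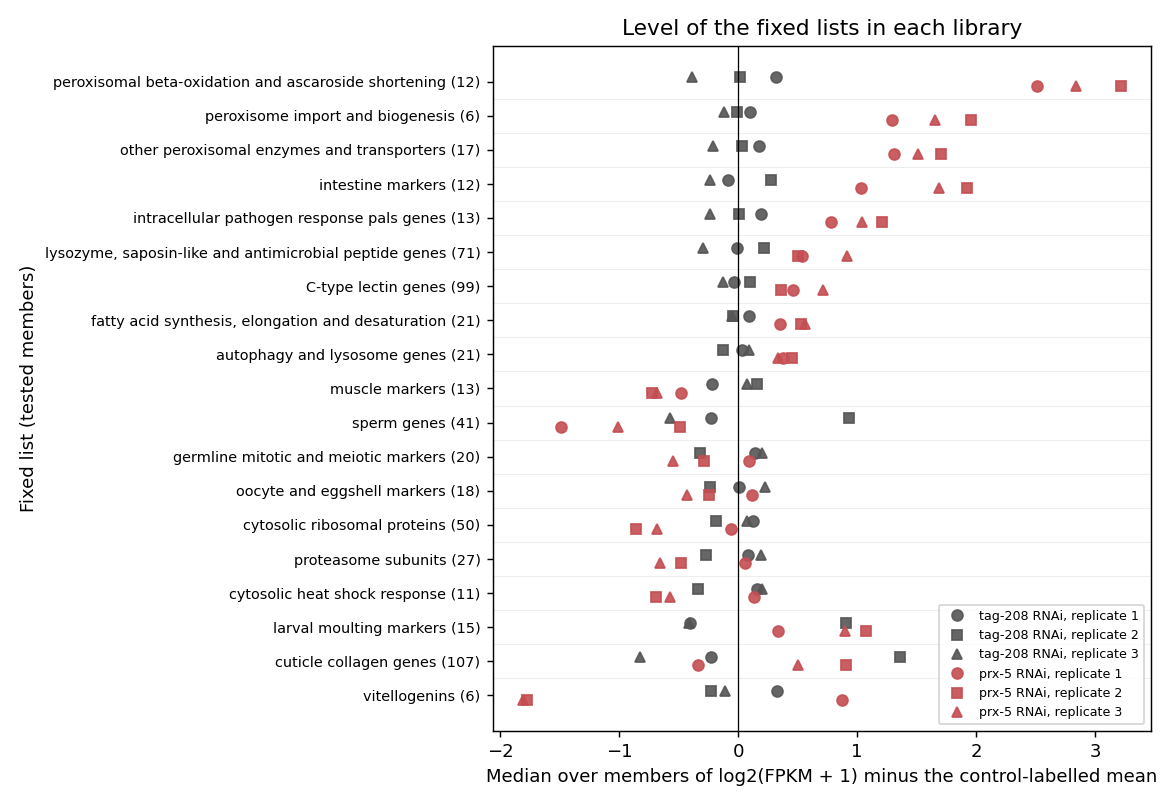
Median over the members of each list of log2(FPKM + 1) minus the control-labelled mean, in each of the 6 libraries, with the number of tested members in brackets. The 3 peroxisomal lists and the intestine markers lie above 1 in all 3 prx-5-labelled libraries, while the proteasome and germline lists of prx-5 replicate 1 lie with control replicates 1 and 3. The vitellogenin point of prx-5 replicate 3 lacks vit-2 and vit-6.

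In all, 21 of 35 lists passed camera with the preset correlation, 12 as higher and 9 as lower, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. By fry, 12 lists passed. These were the 3 peroxisomal lists (fry adjusted p = 0.00697 each), the NHR-49, DAF-16 and autophagy and lysosome lists (0.0109 each) and the pals genes (0.0193). The fatty acid synthesis, cytochrome P450, C-type lectin, intestine and muscle lists passed as well (0.0217 each). Fry read all of them as higher save the muscle markers. The ribosomal (0.181) and sperm (0.237) lists did not pass fry.

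Among the 12 largest rises were 2 genes of the peroxisomal lists, acox-5 and F58F9.7. The enoyl-CoA hydratase family gene ech-9 went from 0.337 ± 0.226 to 69.2 ± 43.97 FPKM (SD, log2 5.45 ± 0.56). With the pseudocount of 1, the saposin-like gene spp-12 had the largest log2 fold change, 5.98 ± 0.68, from 0.113 ± 0.196 to 93.0 ± 73.9 FPKM. It was listed at 0 in 2 of the 3 control-labelled libraries, where the fold depends on the pseudocount, and was not significant in the authors' table (q = 0.322). The glucuronosyltransferases ugt-18 and ugt-16 rose by 5.70 ± 0.52 and 4.84 ± 0.59, and the aspartyl protease asp-12 by 5.47 ± 1.13. The others were W02G9.4 (4.71 ± 0.64), F33H12.7 (4.65 ± 0.66), C50F7.5 (4.52 ± 0.62), K05B2.4 (4.50 ± 0.25) and tkr-2. The tkr-2 locus covered 15.8% of that gene and was listed at 0 in the 3 control-labelled libraries and at 27.4 ± 17.6 FPKM in the others. The control means of ech-9, ugt-18 (0.169 FPKM), K05B2.4 (0.269 FPKM) and tkr-2 also lay under the pseudocount of 1, so their folds and ranks depend on it. The authors' log2 fold changes of ech-9, ugt-18 and K05B2.4 were 7.55, 8.59 and 6.58. Without each library in turn, between 5 and 12 of these calls remained. The 12 largest falls were acdh-2, fat-7, K10C2.8 (-2.59 ± 0.23), T13F3.6 (-2.50 ± 0.26), the collagens col-98, col-124, col-42 and col-103, the hedgehog-related gene grd-3 (-2.37 ± 0.38), C45B2.1 (-2.36 ± 0.34), fipr-13 (-2.09 ± 0.49) and W10G11.3 (-1.99 ± 0.33). Without each library in turn, between 4 and 12 of these calls remained.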

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

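The tests in this part were chosen after the result was seen, except the counts of other splits, which were planned.

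RNA of prx-5 was higher in the libraries labelled prx-5 RNAi, by 1.98 ± 0.22 (SE) on the log2 scale. Neither explanation by handling is argued against by a value in the tables. If reads of the fed double-stranded RNA raised a target, the control's target might be raised in its own group, but sorb-1 stood at 0.7188 ± 0.3086 (SE, prx-5 minus control), and the inserts and their sequencing can differ between targets. If the 2 groups' labels were exchanged, sorb-1 could lie below 0. Its values instead lay higher in all 3 prx-5-labelled libraries than in all 3 controls, the direction that the labels as given predict. Since 0.7188 did not pass the test (adjusted p = 0.232) and the groups were apart in 26.97% of all tested loci, an exchange and the labels as given still cannot be told apart by it. A rise shared with the other import genes is another candidate explanation, and 5 of the 6 other tested import genes rose, with prx-5 at 1.98 and prx-13 at 1.95. Whether the RNAi lowered the protein, or the RNA before the shared rise, was not measured.

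Most called loci were higher in the prx-5-labelled libraries. The missing scaling of the deposited FPKM as the whole cause is argued against, since with the authors' constants 73.07% of calls were still higher, and between 59.99% and 81.8% without each library in turn. Loci with low values stay open as a part of it. With these constants the share higher was 88.0% at a mean of 1 to 5 FPKM and 51.67% at 100 FPKM or more, and the tables cannot tell a difference in measurement from one in the genes that lie at each level. A response to prx-5 RNAi itself was not tested apart from these, nor apart from a response to sorb-1 RNAi in the control.

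The peroxisomal genes were higher in the prx-5-labelled libraries, as were the intestine markers. The germline and oocyte lists passed camera as lower with the preset correlation but not with an estimated one (adjusted p = 0.623 and 0.734), with which none of the 35 lists passed, and their medians overlapped between the groups. A difference in germline content as the whole cause is argued against, since 20 of the 25 calls in the 3 peroxisomal lists held with the germline score as a covariate, with a median of 1.61 for the 35 members against 1.77 without it. For the fatty acid breakdown list, more intestinal RNA to the extent of the markers' median is argued against as the whole cause. Its median rose 1.31 ± 0.2282 (SE) beyond that of the intestine markers, with the groups apart. This SE covers the spread between libraries and not between genes, and single markers rose by more than their median, such as asp-1 (2.53) and vha-6 (2.19). Whether a larger share of intestinal RNA could raise some genes beyond the markers' median was not tested. For the import list (0.08333 ± 0.1731) and the other peroxisomal enzymes (-0.05137 ± 0.2165), a larger share of intestinal RNA and a rise within cells cannot be told apart, because both lists rose about as much as the markers. A response of these genes to prx-5 RNAi stays open as a hypothesis, and a response to sorb-1 RNAi in the control cannot be told apart from it.

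With 3 libraries in each group, the 10 splits of the 6 samples are too few for a share under 0.05. The real split gave 1162 changed loci and the highest other gave 972. Which set of another split counts as higher is arbitrary, so its larger count in 1 direction was used. For higher loci these were 1002 and 822, for lower loci 160 and 822, and for lists past camera 21 and 20. Counting the real split, 1, 1, 2 and 1 of the 10 splits gave a result as large. The split with 972 set control replicate 2 and prx-5 replicates 2 and 3 against the other 3 libraries, and the remaining 8 gave 0 changed loci with limma. That split points to a second structure of the samples, which no label names.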

How the results depend on the processing

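The results under the authors' constants, the germline score, loci of at least 200 bp, loci covering at least 50% of their gene and all loci as listed were chosen after the data were seen; the other alternatives were planned. The log2 fold change of prx-5 stayed past the threshold in all alternatives run, between 1.72 with quantile normalization and 2.19 with a pseudocount of 0.1, and that of tag-208 stayed above 0 and not past it. No called locus changed sign in the alternatives where it was tested. Since the groups of these loci did not overlap, leaving out a library or changing the pseudocount could not have turned a sign. DESeq2 was not run because the tables hold no counts. Since no read numbers are known, loci near 1 FPKM are limited by a depth that cannot be given. The replicate block gave 1253 changed loci, 1043 higher and 210 lower, but the numbers do not pair all samples. The deviations of libraries with the same number had correlations across loci of 0.29, 0.23 and -0.12 for replicates 1, 2 and 3, against 0.33 for control replicate 2 with prx-5 replicate 3. Except where a construction is named, the cause was not tested.

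Counts moved by more than 1.5 times under several settings. Median-ratio scaling gave 697 changed loci and 511 higher, and quantile normalization 536 higher. Sample weights gave 5217, with 3208 higher and 2009 lower. The authors' constants gave 713 and 521 higher, the germline score as a covariate 505, with 399 higher and 106 lower, and all loci as listed 411 lower, since that setting adds the 1004 loci left out. The agreement with the authors' deposited comparison, 958 shared calls with the choices as reported, were 615 with median-ratio scaling, 637 with quantile normalization, 1770 with sample weights, 629 with the authors' constants and 419 with the germline score. Without each library in turn, changed loci ranged from 78 to 1848, higher from 62 to 1462, lower from 16 to 386, and shared calls from 76 to 1332. These fits use fewer samples. The lists past camera numbered 0 with an estimated correlation, and between 15 and 22 in the other alternatives.

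Of the named genes, hsp-16.2 turned to -0.069 (pseudocount 0.1), -0.0075 (pseudocount 0.5), -0.055 (median-ratio), -0.26 (quantile), -0.84 (sample weights), -0.071 (authors' constants) and -0.13 (germline score), and ranged from -0.54 to 0.66 without each library in turn. The value of prx-19 turned to -0.093 (median-ratio), -0.11 (authors' constants) and -0.0031 (sample weights), and ranged from -0.066 to 0.12. Other named genes lost their call most often without control replicate 3 (50), prx-5 replicate 3 (45) and prx-5 replicate 2 (36), and 22 lost it with the germline score.

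Lists whose direction turned had no camera call there, save the RNA interference machinery with the germline score (adjusted p = 0.0429). The early embryo markers turned at an adjusted p of 0.980 (pseudocount 0.1), 0.917 (no filter), 0.984 (median-ratio), 0.978 (no trend), 0.988 (authors' constants) and 0.533 (loci covering at least 50% of their gene). Histones turned at 0.901 (mean of at least 5 FPKM). With quantile normalization, the mitochondrial unfolded protein response, oxidative stress and propionate lists turned at 0.903, 0.867 and 0.903. With sample weights, glutathione S-transferases and collagens turned at 0.885 and 0.630. With the germline score, the mitochondrial response and glutathione S-transferases turned at 0.828 each, and oxidative stress and moulting at 0.931 each. Without each library in turn, camera adjusted p ranged from 0.757 to 0.998 (early embryo), 0.303 to 0.890 (glutathione S-transferases), 0.218 to 0.998 (mitochondrial response), 0.385 to 0.899 (oxidative stress), 8.69e-06 to 0.374 (collagens) and 0.0561 to 0.989 (RNA interference machinery).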

Other observations

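The tests of gene families were chosen after the results were seen, and the families and genes named here were picked after their values were seen. The asp and cpr protease families had an excess of higher calls in the prx-5-labelled libraries, and the nas and nep families did not. Of 12 tested aspartyl protease (asp) genes, 10 rose and 0 fell (Fisher's exact test, one-sided, adjusted p = 7.02e-08), with a median log2 fold change of 2.32; 3 of them are also in the fixed lists. Of these 10 calls, 3 were kept without control replicate 1, 0 without control replicate 3, and 1 each without prx-5 replicates 2 and 3. The gene asp-6 went from 447 ± 148 to 3867 ± 1777 FPKM (SD, n = 3). Of 6 cathepsin B-like (cpr) genes, 5 rose (exact adjusted p = 8.91e-04), with 0 kept without control replicate 3, prx-5 replicate 2 or prx-5 replicate 3, and cpr-4 went from 448 ± 191 to 2804 ± 1258 FPKM. Of 20 astacin (nas) genes, 0 rose and 1 fell, and of 14 neprilysin (nep) genes, 3 rose (exact adjusted p = 1 each). Of 6 scavenger receptor (scav) genes, 4 rose (exact adjusted p = 0.0190), and of 12 galectin (lec) genes, 5 rose (exact adjusted p = 0.0447), among them lec-8, from 73.7 ± 13.6 to 447 ± 193 FPKM. The intestine markers rose by a median of 1.52 in the same libraries.

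Other families with an excess of higher calls were of several kinds. Of 165 nuclear hormone receptor (nhr) genes, 33 rose and 0 fell (exact adjusted p = 3.03e-05), with 11 of the 33 kept under the authors' constants. Among them nhr-79 went from 2.71 ± 0.86 to 11.28 ± 2.05 FPKM. Of 20 math genes, 10 rose (exact adjusted p = 5.55e-05, 4 kept), and of 116 fbxa genes, which encode F-box proteins, 23 rose (exact adjusted p = 0.00109, 8 kept). The F-box families fbxb and fbxc had 0 higher of 67 and 0 of 26, and bath, btb and the homeobox family ceh had 3 of 39, 2 of 17 and 2 of 42 (exact adjusted p = 1 each). All 33 nhr and all 10 math calls and 22 of the 23 fbxa calls had a mean under 20 FPKM, where most calls of any kind were higher (92.49% at 1 to 5 FPKM and 89.74% at 5 to 20). The intestine markers were higher in the same libraries. Of 11 nspc genes, 7 rose (exact adjusted p = 2.61e-04, 5 kept), and of 7 ech genes, 4 rose (exact adjusted p = 0.0360, 4 kept). Of 9 hedgehog-related grd genes, 3 fell (exact adjusted p = 0.00574, 3 kept), among them grd-5, from 150 ± 28.4 to 45.05 ± 13.3 FPKM. Without control replicate 3, 0 of the nhr, math, nspc and grd calls, 1 each of the fbxa, scav and lec calls and 2 of the ech calls were kept. In all, 13 of 270 families had an excess of higher calls and 3 of lower calls, and clec, spp, prx and ugt (higher) and col and fipr (lower) lie within the fixed lists, apart from prx-5 itself. Medians of the families past the test kept their sign under the 3 scalings, save that of col, which was 0.22 and turned to -0.06 with quantile normalization. Genes of a family often lie together and respond alike, which the exact test does not take into account.

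The libraries also differed along a line that the labels do not name. Control replicate 2 lay with prx-5 replicates 2 and 3 in the moulting markers (0.91, against 1.07 and 0.89) and the collagens (1.36, against 0.91 and 0.50). It also lay with them in the germline markers (-0.32, against -0.29 and -0.55), but not in the sperm genes (0.93, against -0.49 and -1.01). Prx-5 replicate 1 lay with control replicates 1 and 3 in the collagens (-0.34, against -0.22 and -0.82), the germline markers (0.09, against 0.14 and 0.20) and the proteasome (0.05, against 0.09 and 0.19), but not in the moulting markers (0.34, against -0.40 and -0.41). Age or stage of the worms was not tested.

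Among the 1004 loci left out, where the labels differed between files or the group value missed the tolerance, 920 passed the filter on low values. With all loci as listed, 248 of these (26.96%) would be called, 239 of them lower, against 9.15% of the loci used. In the authors' table, 43 of 2034 significant loci were among those left out.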
